A study of Homo sapiens with 12 samples.

How the data were processed

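The series holds 12 Affymetrix 3′ expression arrays of RNA from SH-SY5Y cells, in 4 groups of 3 by the labels: oligomeric Aβ with an incubation of 6 h, its control, fibrillar Aβ with an incubation of 24 h, and its control. The deposited values are log2 probe set signals, made with MAS5 per the submitters' processing notes, which state no version. The trimmed mean of the linear signal, from 2% to 98%, was equal between arrays, so each array had been scaled to a single target before the log was taken, and the values were used without further normalization. Detection calls were not used here. For arrays the number limits the precision, and the median standard error of a change between 2 groups was 0.13 on the log2 scale.

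Of the probe sets, 62 were controls, 41097 carried 1 gene symbol, 1801 carried several and 11721 carried none. Probe sets with a mean over the 12 arrays at or above the median (log2 3.78, a signal of 13.8) were kept, 27307 in all. For each gene the brightest probe set with 1 symbol was tested, which gave 11774 genes, 5838 of them with more than 1 probe set above the filter. The 5184 kept probe sets with several or no symbols were tested apart from the genes. Control probe sets gave the array measures: the 3′ less 5′ values of GAPDH and ACTB, the spike-ins and 18S ribosomal RNA, compared by exact permutation tests adjusted over 18 comparisons.

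A group-means model was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8, to read the values), with a prior variance that followed the mean level, and Benjamini-Hochberg adjusted p-values under 0.05 were called. The 5 contrasts were oligomeric Aβ against control at 6 h, fibrillar Aβ against control at 24 h, the difference of these responses, their average, and the 24 h against the 6 h controls. The labels do not say that a replicate number marks a shared culture or day, so the numbers were not used as pairs. Gene lists, 31 in number, were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested, which left 28, with adjustment over all lists and contrasts. The estimated correlation and fry, a test of whether a list moves on balance in a single direction, were run as alternatives.

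The groups, contrasts, filter, lists, named genes and alternative settings were fixed before the data were examined. The named genes were, for the oligomer and fibril contrasts, up to 12 rising and 12 falling genes with the largest change among those called with groups fully apart, filled to 12 by the smallest p where fewer passed. For the other contrasts they were up to 5 in each direction, filled to 4. For each list described they were up to 2 members in each direction with the smallest p, and APP, BACE1, MAPT, HMOX1, DDIT3, HSPA5, CDKN1A and FOS were always included. Uncharacterised genes were counted and not named.

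The procedure was tested on simulated data of the same size with 100 genes changed 1.5-fold and 100 changed 2-fold in each arm. With oligomers 46% and 72% were recovered, with 7 false among 125 calls, and with fibrils 42% and 80%, with 4 false among 126. A list shifted by 0.3 was called in both arms, and 0 other lists were. Noise was drawn independently for each gene, with the same spread in all groups. So the simulation cannot show how calls of lists or genes behave where genes vary together or the spread differs between groups.

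The alternative settings fixed then were quantile normalization, centring on the array median, no filter or a filter at the 75th percentile, and the mean of a gene's probe sets or every probe set. They also included a constant or a robust prior variance, array quality weights, the 2 compared groups alone, the replicate number as a block, a 1.5-fold or a looser threshold, and each array left out in turn. Chosen after the data were seen were the mean 3′ less 5′ value as a covariate, the 24 h arrays alone with array weights, and log2 of the signal plus 16. Genome positions are not given, because the arrays were read by gene symbol alone.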

Results

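Gene expression was measured in SH-SY5Y cells, a human neuroblastoma line often used as a neuron-like model, on 12 Affymetrix arrays. Per the labels, cells had received an oligomeric preparation of amyloid-β (Aβ, the peptide that forms the plaques of Alzheimer's disease) with an incubation of 6 h, or a fibrillar preparation with an incubation of 24 h. Each preparation had controls of its own time, and each of the 4 groups had 3 arrays. The form of the peptide and the hours always changed together, and the labels do not say whether the incubation is the ageing of the peptide or the exposure of the cells. The values are log2 MAS5 signals. Their median per array lay between 3.89 and 4.12, and the number of arrays limits the precision. A mean level at or above log2 3.78 left 11774 genes, each read from its brightest probe set. The p-values measure only the spread between these samples, because the labels do not say that the replicates were separate cultures.

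The 12 arrays parted by time before they parted by treatment. The first principal component held 25.6% of the variance and separated the 6 arrays of 24 h from the 6 arrays of 6 h. The next component held 11.8%, with scores of 8.12 to 19.4 in the fibrillar arrays against −18.2 to −7.67 in the 24 h controls, while the oligomeric arrays overlapped the 6 h controls. The single probe set read for the 5′ part of 18S ribosomal RNA was higher at 24 h by 1.66 on the log2 scale, with means of 11.7 and 10.1 (two-sided exact permutation test, p = 0.00216, the smallest that 6 against 6 arrays allow, adjusted p = 0.039 over 18 comparisons of array measures). Fibrillar replicate 1 had the highest 3′ to 5′ differences of the 24 h arrays, 0.81 for GAPDH and 3.06 for ACTB, against 0.47 to 0.52 and 2.34 to 2.65 in the 24 h controls. Between the fibrillar and 24 h control groups these differences were 0.15 and 0.25 (exact permutation p = 0.3 for each, where 0.1 is the smallest that 3 against 3 arrays allow). The 18S signal was higher in the fibrillar arrays by 0.20, with means of 11.8 and 11.6 and groups fully apart (exact permutation p = 0.1, adjusted p = 0.362).

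The comparison of oligomeric Aβ with control at 6 h asked which genes respond to the soluble aggregates. None passed the test. FOS, an immediate early transcription factor, had a log2 signal of 4.74 ± 0.21 (SD, n = 3) with oligomers and 4.51 ± 0.53 in the controls. APP, the gene of the Aβ precursor, differed by 0.13 (SE 0.17), BACE1, the β-secretase that cleaves it, by 0.17 (SE 0.11), and MAPT, the gene of tau, by 0.31 (SE 0.22). Each SE and p-value uses a spread per gene shared by the 4 groups. For APP the SDs were 0.02 and 0.07 at 6 h, with groups fully apart, against 0.53 with fibrils. Its SE is therefore larger than the spread of the 6 h arrays would give. DDIT3, a stress-induced transcription factor also called CHOP, had the lower mean with oligomers, −0.55 (SE 0.22). The chaperone gene HSPA5 differed by 0.04 (SE 0.07), and the cell cycle inhibitor CDKN1A by −0.07 (SE 0.14), none of which passed. The smallest p-values belonged to SETD1B, a histone H3 lysine methyltransferase (−0.69, SE 0.13), and SLC35H1 (−0.76, SE 0.15), both with an adjusted p of 0.551. Behind them, with larger adjusted p-values, came the rest of the 12 genes named by rank: HOXD4 (0.54), DBH, the enzyme of noradrenaline synthesis (0.38), CISH (0.69), AVIL (1.08), TRMT2B (0.72) and GTF2H3 (0.46) with higher means, and CHST12 (−0.51), TXNDC12 (−0.30), SUPT7L (−0.32) and WDR35 (−0.38) with lower means. The probe sets of CISH, AVIL and GTF2H3 carry the array maker's mark for possible cross-hybridization. The other 3 tested probe sets of BACE1 had changes of the opposite sign, as did the 1 other of SLC35H1, CISH and GTF2H3. The 1 other of CHST12, AVIL and WDR35 had the same sign.

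With limma, 0 of 11774 genes passed an adjusted p of 0.05 in the oligomer comparison, and 327 had an unadjusted p below 0.05, where 589 would by chance alone. The groups lay fully apart for 7.36% of genes, against 10% by chance. In simulated data of the same size, with noise independent between genes, 46% of added 1.5-fold changes and 72% of added 2-fold changes were recovered. None of the 28 gene lists passed with all arrays in the main fit. Their median changes ran from −0.04 to 0.10, and the lowest adjusted p was 0.138, for the cytosolic ribosomal proteins. Single arrays decided this for 5 lists. Ribosomal proteins were called higher without oligomeric replicate 1 (adjusted p = 0.00398) or 2 (7.53e-05) and lower without replicate 3 (0.0453). Mitosis genes were called lower without oligomeric replicate 2 (1.89e-07) or control 6 h replicate 3 (8.1e-05), and oxidative phosphorylation genes without oligomeric replicate 2 (0.0303) or 3 (0.00217) or control 6 h replicate 3 (0.0087). Proteasome genes were called lower without oligomeric replicate 2 (0.00548), and ATF4 genes higher without control 6 h replicate 2 (0.0337). These adjusted p-values came from camera at the preset correlation of 0.01, and the estimated correlation was not run with arrays left out. With all arrays and the estimated correlation, 0 lists passed in any of the 5 contrasts. With all arrays and the replicate number as a block, mitosis genes were called lower (camera adjusted p = 0.0354). No member of any list passed over all genes, and adjusted over the list alone 1 member, of the noradrenergic markers, had a higher level.

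**Figure D1:**
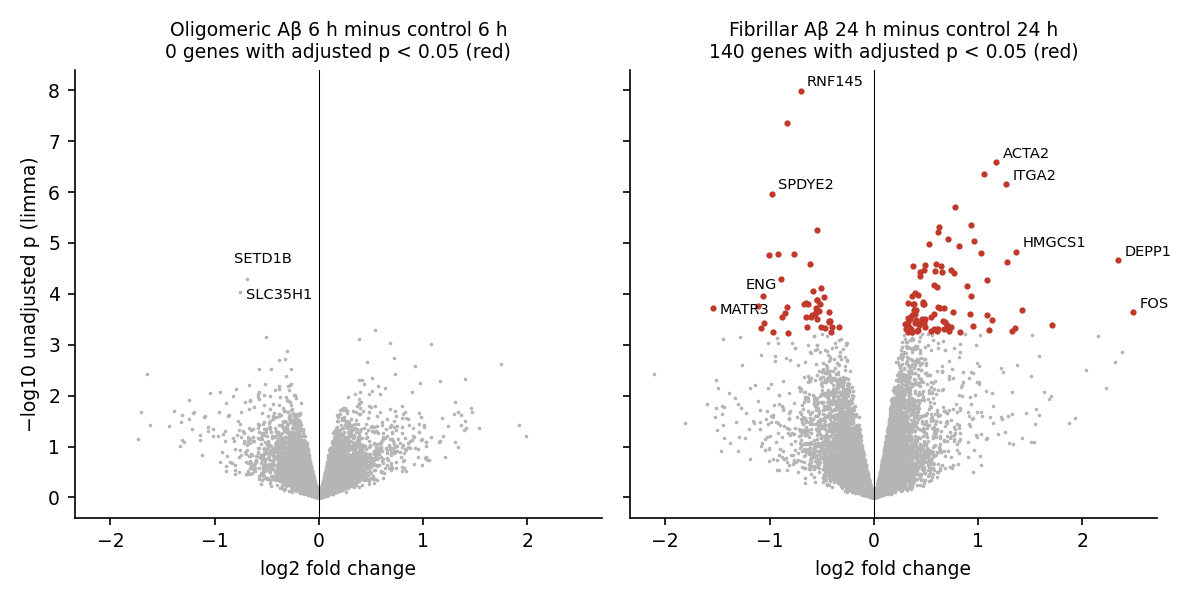
Log2 fold change (horizontal axis) against the negative log10 of the unadjusted limma p (vertical axis) for 11774 genes, with oligomeric Aβ at 6 h on the left and fibrillar Aβ at 24 h on the right. Red points mark genes with an adjusted p under 0.05, which were 0 on the left and 140 on the right.

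The comparison of fibrillar Aβ with control at 24 h asked the same of the insoluble aggregates, and here 94 genes rose and 46 fell. The largest rise was that of FOS, an AP-1 subunit, from 4.01 ± 0.61 to 6.50 ± 1.47 (SD, n = 3), a log2 change of 2.49 (SE 0.53, adjusted p = 0.0366). DEPP1, a regulator of autophagy, rose by 2.34 (SE 0.40, adjusted p = 0.0121), from 2.10 ± 0.34, a level under the filter, to 4.44 ± 0.34. ITGA2, the α2 subunit of a collagen-binding integrin, rose by 1.27 (SE 0.16, adjusted p = 0.00163), from 8.40 ± 0.15 to 9.66 ± 0.47, and ACTA2, smooth muscle actin, by 1.17 (SE 0.14, adjusted p = 0.00101), from 7.39 ± 0.19 to 8.57 ± 0.22. The other leading risers were the growth factor gene PDGFA (1.71), ZCCHC12 (1.42), GBP3, an interferon-inducible GTPase (1.35), the adaptor gene SH2D3C (1.33) and FAM43A (1.28), with adjusted p-values from 0.0124 to 0.0478. The control means of PDGFA (2.92 ± 0.45) and GBP3 (3.51 ± 0.27) were under the filter level, and that of ZCCHC12 (3.78 ± 0.36) was at it, so the size of their changes rests on low values. The change of FOS ran from 1.66 to 3.05 when single arrays were left out. Each SE uses a spread per gene shared by the 4 groups, and for FOS the SD was largest in the fibrillar arrays. Of the 6 fits that left out a 24 h array, DEPP1 and FAM43A were called in 4, FOS, PDGFA, ZCCHC12 and SH2D3C in 1 (limma adjusted p up to 0.124, 0.179, 0.179 and 0.205) and GBP3 in 0 (up to 0.181). With the mean of probe sets the calls of FOS (adjusted p = 0.0575), PDGFA (0.0564), GBP3 (0.0531) and SH2D3C (0.0626) were lost although their changes were the same.

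Among the genes that fell, ENG, a co-receptor for transforming growth factor β, fell by 1.11 (SE 0.23), from 5.67 ± 0.15 to 4.56 ± 0.39 (SD, n = 3), and TGFB3, a gene of the same growth factor family, fell by 0.97 (SE 0.23), with adjusted p-values of 0.0338 and 0.0486. The call of TGFB3 was lost after quantile normalization (adjusted p = 0.0618) and after median centring (0.0532), and of the 6 fits that left out a 24 h array ENG was called in 1 and TGFB3 in 0 (limma adjusted p up to 0.111 and 0.221). MATR3, a nuclear matrix protein that binds RNA, fell by 1.54 (SE 0.32, adjusted p = 0.0341). Falls also passed for HIRA, a histone chaperone (−1.09), XRCC2, a homologous recombination protein (−1.07), SLFN5 (−1.05), GPS1, a subunit of the COP9 signalosome (−0.92), THRAP3 (−0.85) and LMO3, a LIM domain transcription cofactor (−0.83), with adjusted p-values from 0.00995 to 0.0456. The fall of THRAP3 was −0.09 as the mean of its 4 tested probe sets (adjusted p = 0.894). MATR3 (0.0564), HIRA (0.0756) and SLFN5 (0.0564), each with 1 tested probe set, lost their call in that setting with their changes the same. With single 24 h arrays left out MATR3, HIRA and XRCC2 were called in 1 of 6 fits, SLFN5, THRAP3 and LMO3 in 2 and GPS1 in 4. SMG1P5 (−1.01), SPDYE2 (−0.97) and POLR2J4 (−0.89) also fell, but they belong to families of near-identical copies, so their probe sets may read several genes at once. The probe sets of JUN, XRCC2 and SLFN5 carry the array maker's mark for possible cross-hybridization.

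**Figure D2:**
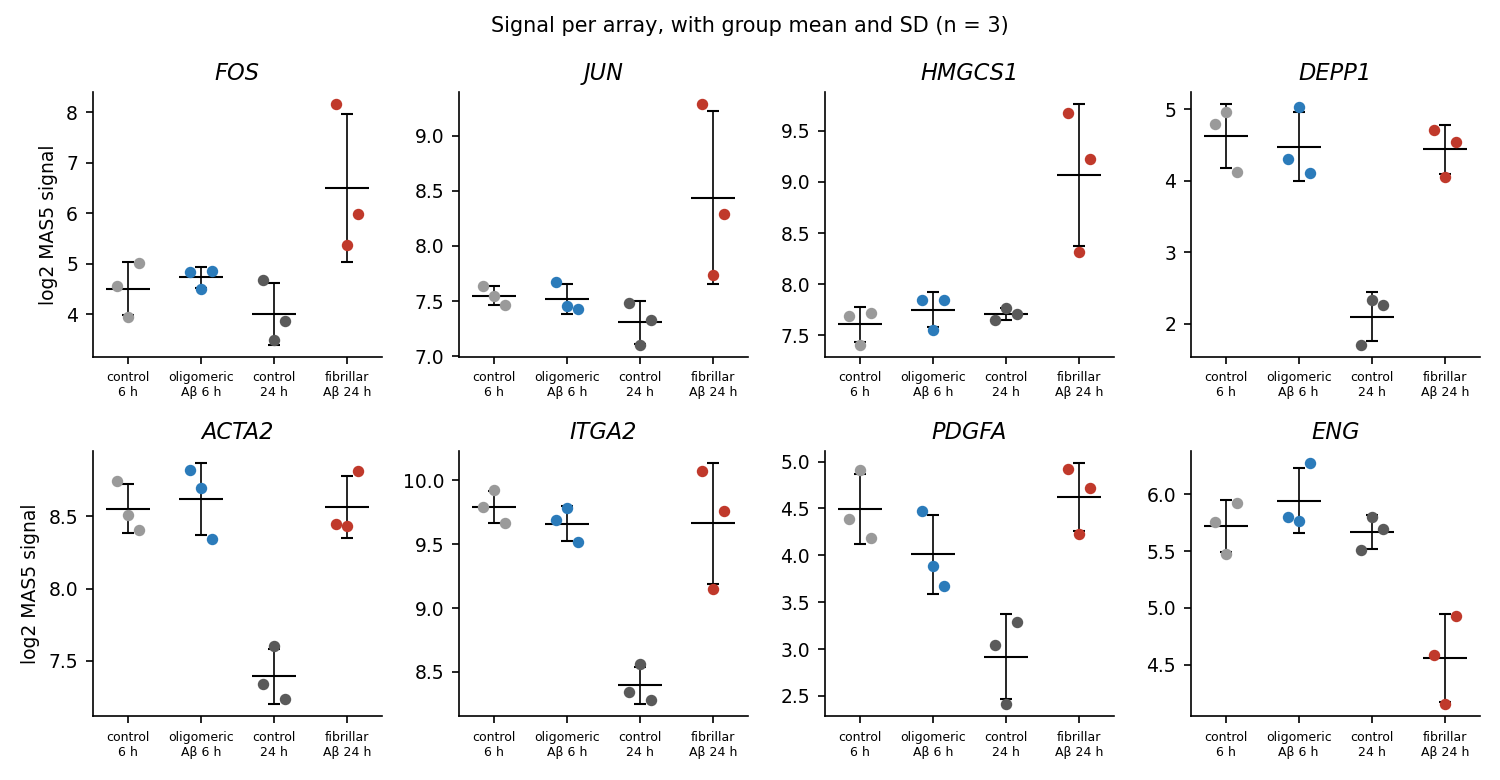
Log2 MAS5 signal of 8 genes in each of the 12 arrays, with the group mean (line) and SD (bar), n = 3. FOS was 8.16 in fibrillar replicate 1 and 5.36 and 5.98 in the other 2 fibrillar arrays, against 3.49 to 4.69 in the 24 h controls, while DEPP1, ACTA2, ITGA2 and PDGFA were lower in the 24 h controls than in the 3 other groups.

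The list of immediate early genes had a higher level with fibrils. Of 26 tested members, 5 rose and 1 fell over all genes, and 16 rose and 1 fell adjusted over the list alone. KLF6 rose by 0.93 (SE 0.14), JUND by 0.71 (SE 0.11), JUN by 1.13 (SE 0.25) and ATF3 by 1.10 (SE 0.26), while MYC fell by 0.54 (SE 0.11). The calls of JUN and ATF3 were lost with the mean of probe sets (adjusted p = 0.0626 and 0.241). Without fibrillar replicate 1 their changes were 0.71 and 0.70, and of the 6 fits that left out a 24 h array JUN was called in 2 and ATF3 in 1. The list had a median change of 0.50 (adjusted p = 3.82e-12, adjusted p = 0.806 with an estimated correlation). Its mean in fibrillar replicate 1, the array with the highest 3′ to 5′ differences, lay 1.26 above the controls, against 0.26 and 0.49 in the other 2 fibrillar arrays.

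Genes of cholesterol synthesis and other SREBP2 targets also rose, 8 of 26 over all genes and 13 adjusted over the list alone, with none that fell. HMGCS1, which makes the precursor of mevalonate, rose by 1.36 (SE 0.22), from 7.71 ± 0.06 to 9.07 ± 0.69 (SD, n = 3; adjusted p = 0.00995), and MSMO1, a sterol demethylation enzyme, rose by 1.03 (SE 0.17). The call of HMGCS1 was lost with the mean of probe sets (adjusted p = 0.0626) and stood in 4 of the 6 fits that left out a 24 h array. The list median was 0.32 (adjusted p = 5.95e-08, adjusted p = 0.806 with an estimated correlation), and the list means of the 3 fibrillar arrays lay 0.52, 0.12 and 0.31 above the controls, again highest in replicate 1. Among 36 genes of the ATF4 stress response, 4 rose over all genes and 13 adjusted over the list alone, among them the asparagine synthetase gene ASNS (0.37, SE 0.08) and DDIT3 (0.95, SE 0.22). The call of DDIT3, which has 1 tested probe set, was lost in the setting with the mean of probe sets (adjusted p = 0.0564) with its change the same, and stood in 1 of the 6 fits that left out a 24 h array. The ATF4 list had a median of 0.20 (adjusted p = 1.32e-06, adjusted p = 0.806 with an estimated correlation), and its 3 fibrillar arrays lay 0.23, 0.21 and 0.20 above the controls.

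Shifts were called for 3 more lists. In the hypoxia and glycolysis list, VEGFA (0.41) and EGLN1 (0.31) rose among 36 genes, 10 rose adjusted over the list alone, and the median was 0.17 (adjusted p = 0.00108, adjusted p = 0.927 with an estimated correlation). The call was lost without fibrillar replicate 2 (adjusted p = 0.24). In the NF-κB list, NFKBIZ (0.68) and TNIP1 (0.42), both of which restrain or tune NF-κB signalling, rose among 15 genes, 4 rose adjusted over the list alone, and the median was 0.29 (adjusted p = 0.011, adjusted p = 0.806 with an estimated correlation), a call lost without fibrillar replicate 1 (adjusted p = 0.149). Nuclear-encoded oxidative phosphorylation genes had a lower list level, with a median of −0.03 and 0 of 43 members called by limma over all genes, 1 of which fell adjusted over the list alone (adjusted p = 0.038, adjusted p = 0.96 with an estimated correlation). That call was lost without fibrillar replicate 3 (0.237), control 24 h replicate 2 (0.163) or control 24 h replicate 3 (0.111), and after median centring (0.109). Some members, such as ATF3 and DDIT3, stand in more than 1 list or were also named by rank.

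**Figure D3:**
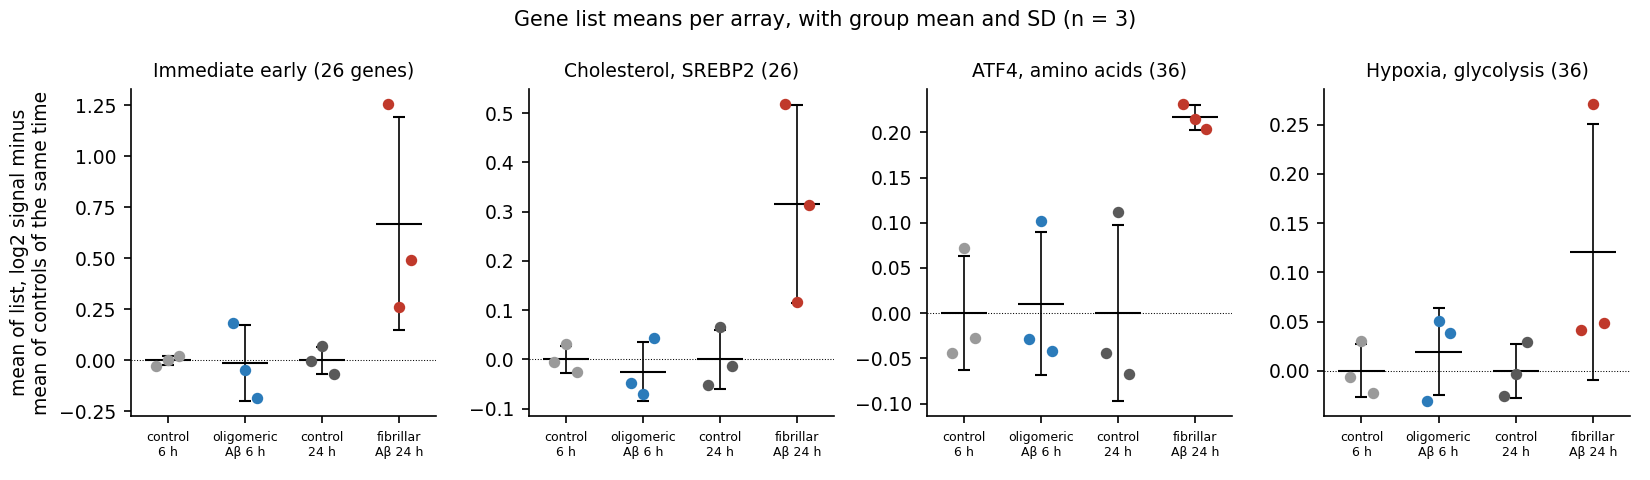
Mean log2 signal of 4 gene lists per array, less the mean of the controls of the same time, with the group mean (line) and SD (bar), n = 3. In the fibrillar arrays the immediate early list lay 0.26 to 1.26 above the control mean and the ATF4 list 0.20 to 0.23, while the oligomeric arrays lay around 0.

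Amyloid-related genes showed little in common. APP had a higher level with fibrils (0.74, SE 0.17, adjusted p = 0.0454), but its fibrillar and control values overlapped and 1 of its other 2 tested probe sets went the other way, with a change of 0.30 and adjusted p = 0.408 for the mean of the probe sets, and an adjusted p of 0.0619 after quantile normalization. It was called in 1 of the 6 fits that left out a 24 h array. APH1A, a γ-secretase subunit, fell by 0.41 (adjusted p = 0.0486). Over 18 genes of precursor processing, 1 rose and 1 fell, 2 rose and 1 fell adjusted over the list alone, and the list did not pass (median 0.07, adjusted p = 0.523). The 15 genes of Aβ binding, uptake and breakdown had 0 called by limma over all genes, 2 up and 1 down adjusted over the list alone, and a median of 0.14 (adjusted p = 0.471). In the list of tau, microtubule and neurofilament genes, TUBB2A rose by 0.44 among 25 members, 2 rose and 1 fell adjusted over the list alone, and the median was 0.02 (adjusted p = 0.523). BACE1 (0.13, adjusted p = 0.693), MAPT (−0.12, adjusted p = 0.859), HSPA5 (0.06, adjusted p = 0.781) and CDKN1A (0.43, adjusted p = 0.157) did not pass, and HMOX1 was below the filter.

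The remaining lists did not pass with fibrils when all arrays were used. Mitosis genes were called lower without fibrillar replicate 2 (adjusted p = 0.00101) or control 24 h replicate 3 (0.000692) and after quantile normalization (0.0401), and S phase genes without fibrillar replicate 2 (0.0195) or control 24 h replicate 3 (0.0283). The stress lists had medians of 0.11 for the endoplasmic reticulum unfolded protein response (adjusted p = 0.225), 0.05 for the heat shock response (0.867), 0.03 for NRF2 targets (0.671), −0.04 for antioxidant enzymes (0.373) and −0.12 for metallothioneins (adjusted p = 0.977), with a median above and a mean below 0 for heat shock. For p53 targets, of which GADD45A rose by 0.67, the median was 0.06 (adjusted p = 0.383), and for interferon response genes −0.05 (0.977). Growth lists gave −0.00054 for S phase (adjusted p = 0.683), −0.05 for mitosis (0.226), 0.0018 for ribosomal proteins (0.894), −0.07 for ribosome biogenesis (0.523), 0.01 for splicing factors (0.894) and −0.17 for replication-dependent histones (0.386). Synaptic genes (0.06, adjusted p = 0.724), calcium handling (0.02, 0.977), autophagy and lysosome (0.0026, 0.864), proteasome (0.0084, 0.977), noradrenergic markers (0.01, 0.977) and mesenchymal markers (0.02, 0.523) did not pass either. Markers of epithelial, blood or endothelial, and glial cells had only 3, 3 and 2 members above the filter and were not tested as lists.

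Of the 140 genes, 139 had fibrillar values that lay fully to 1 side of the control values, and 19.7% of all genes did, against 10% by chance. The change was at least 1.5-fold for 74 and at least 2-fold for 22. The count moved to 7 without the mean-variance trend, 79 without a filter, 62 with the mean of probe sets, 35 with the 2 groups alone and 268 with array weights. It was 39 with the 3′ to 5′ ratio as a covariate, which was chosen after the data were seen. Leaving out a fibrillar array gave 87 without replicate 1, 185 without replicate 2 and 21 without replicate 3, and leaving out a 24 h control gave 14, 64 and 28 for replicates 1, 2 and 3. Of the 26 named genes 12, 8 and 20 lost their call without fibrillar replicates 1, 2 and 3 and 23, 15 and 18 without 24 h control replicates 1, 2 and 3. With the mean of probe sets 13 lost it. Of the 26, ACTA2, ITGA2 and SPDYE2 were called in all 6 fits that left out an array, and over all genes 11 were.

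The difference between the fibrillar and oligomeric responses, each against its own controls, tested whether the preparations act apart, with form and hours confounded. ITGA2 differed by 1.40 (SE 0.23, adjusted p = 0.0367), with −0.13 for oligomers and 1.27 for fibrils. Its level was 9.66 with either preparation, against controls of 9.79 at 6 h and 8.40 at 24 h. Lower responses to fibrils than to oligomers were those of GTF2H3, a subunit of transcription factor IIH (−1.22, SE 0.18, adjusted p = 0.0219), and SPDYE2 (−1.11, SE 0.18, adjusted p = 0.0367). So were those of LPCAT1, a phospholipid remodelling enzyme (−0.77, SE 0.12, adjusted p = 0.0367), and RNF145, a sterol-responsive ubiquitin ligase (−0.65, SE 0.09, adjusted p = 0.0219). The levels of GTF2H3 were 8.87 with fibrils and 8.96 with oligomers, against controls of 9.63 at 24 h and 8.50 at 6 h. For ITGA2 and GTF2H3 the difference thus lay mainly between the controls. With fibrils and oligomers the levels were 7.04 and 7.67 for SPDYE2, 7.88 and 8.66 for LPCAT1 and 10.1 and 10.5 for RNF145. The other tested probe set of GTF2H3 had a change of the opposite sign. These were the 5 genes past the limma threshold, and 1004 had an unadjusted p below 0.05. With the mean of probe sets ITGA2 (1.01, adjusted p = 0.167), GTF2H3 (−0.54, 0.349), SPDYE2 (−1.11 as before, 0.0524) and RNF145 (−0.64, 0.135) lost their call. After quantile normalization ITGA2 (0.0517) and SPDYE2 (0.0527) did, and after median centring SPDYE2 (0.0501). Each of the 5 was called in only 2 or 3 of the 12 fits that left out an array, in which the count ran from 0 to 64. It was 0 without any of the 3 oligomeric arrays, control 6 h replicate 2 or 3, fibrillar replicate 3, or control 24 h replicate 1 or 3, and it was 1 without control 6 h replicate 1, 29 without fibrillar replicate 1 and 64 without fibrillar replicate 2. The difference for FOS was 2.26 (SE 0.75, adjusted p = 0.345), and it ran from 1.43 to 2.83 when single arrays were left out, with 0 calls.

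Lists with a larger fibrillar than oligomeric shift were the immediate early genes (mean difference 0.68, adjusted p = 7.12e-10, adjusted p = 0.806 with an estimated correlation), cholesterol genes (0.34, adjusted p = 1.02e-06, and adjusted p = 0.806 with an estimated correlation), ATF4 genes (0.21, adjusted p = 0.00096, and adjusted p = 0.927 with an estimated correlation) and hypoxia genes (0.10, adjusted p = 0.0259, and adjusted p = 0.96 with an estimated correlation). With limma 0 of their members passed over all genes, and 9 rose and 1 fell, 9 rose, 6 rose and 0 did adjusted over the list alone. The hypoxia call was lost without oligomeric replicate 1 (adjusted p = 0.14), control 6 h replicate 2 (0.128), fibrillar replicate 2 (0.654) or control 24 h replicate 1 (0.0509), after quantile normalization (0.0643) and with the mean of probe sets (0.0535). Across genes, which are not independent replicates, the changes with oligomers and fibrils were unrelated (Pearson r = −0.02, Spearman rho = −0.01), and 60 of 100 splits of the arrays within each time gave an r at least as large. Of the 140 fibrillar genes, 62 (44.3%) had the same sign with oligomers, 0 were called in both, and their median change with oligomers was −0.02 for the risers and 0.03 for the fallers.

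Averaged over both preparations, 6 treated against 6 control arrays, 3 genes passed limma and 987 had an unadjusted p below 0.05. ACTA2 was higher by 0.62 (SE 0.10, adjusted p = 0.0395), and LPCAT1 (−0.44, SE 0.06, adjusted p = 0.0107) and RNF145 (−0.38, SE 0.05, adjusted p = 0.00531) were lower. All 3 took nearly their whole change from the fibrillar arm, as their changes with oligomers were 0.07, −0.06 and −0.05. The next gene, RHOB, a stress-induced small GTPase, had 0.52 (adjusted p = 0.0933). RNF145 was called in all 12 fits that left out an array, LPCAT1 in 10 and ACTA2 in 5. With the mean of probe sets ACTA2 (0.62 as before) and RNF145 (−0.37) had adjusted p-values of 0.0772 and 0.147. The count was 1 without oligomeric replicate 2 or control 24 h replicate 3, 5 without control 6 h replicate 2, 10 without fibrillar replicate 1 and 32 without fibrillar replicate 2. Called for the average were 5 lists with higher levels, immediate early, ATF4, cholesterol, hypoxia and NF-κB genes, and 2 with lower levels, oxidative phosphorylation and mitosis genes, and 0 of the 28 passed with an estimated correlation (lowest adjusted p = 0.806 with an estimated correlation). With oligomers alone 0 of the 28 lists passed in the main fit, so these calls do not show a shift that both preparations share. Without oligomeric replicate 1 the NF-κB (adjusted p = 0.0766), oxidative phosphorylation (0.384) and mitosis (0.361) calls were lost, and without fibrillar replicate 1 the NF-κB (0.0643) and mitosis (0.0956) calls. Without fibrillar replicate 2 the hypoxia call (0.127) was lost, and without fibrillar replicate 3 the oxidative phosphorylation (0.057) and mitosis (0.619) calls. Mitosis was also lost without oligomeric replicate 3 (0.501), control 6 h replicate 1 (0.0583) or 2 (0.514), or control 24 h replicate 2 (0.732), after median centring (0.0615) and with the mean of probe sets (0.136), and oxidative phosphorylation without control 6 h replicate 2 (0.0714).

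The controls of 24 h and 6 h show the background against which both responses stand, and they differed more than any treated group did from its control. Between them 443 genes rose and 932 fell. MALL, a membrane raft protein gene, had the largest fall, 4.56 on the log2 scale, from 6.13 ± 0.15 to 1.57 ± 2.25 (SD, n = 3; adjusted p = 0.00184), a level below the filter. DEPP1 fell by 2.53, the chemokine gene CCL2 fell by 2.48, TMEM158 fell by 2.41 and LYG1 fell by 2.38. The 24 h levels of DEPP1 (2.10), TMEM158 (3.19) and LYG1 (2.20) and the 6 h level of ATP2B2 (3.30) were also below the filter, so these sizes rest on low values. The largest rises were those of NXPE3 (1.37), GINS4, a DNA replication factor (1.37), the calcium pump gene ATP2B2 (1.36), the transcription factor gene SOX5 (1.20) and SOSTDC1 (1.19), with adjusted p-values from 0.00848 to 0.0464. APP fell by 0.89 (SE 0.17, adjusted p = 0.00297), but with the mean of probe sets its change was −0.14 (adjusted p = 0.599), and that of GINS4 was 0.43 (adjusted p = 0.442). Left-out arrays ended several of these calls: NXPE3, ATP2B2 and SOSTDC1 lost theirs without control 6 h replicate 1 (adjusted p = 0.093, 0.13 and 0.154) or any of the 24 h controls (highest 0.0552, 0.142 and 0.128). SOX5 lost its call without control 6 h replicate 1 (0.073) or 3 (0.0616) or control 24 h replicate 1 (0.101) or 3 (0.0716), and LYG1 lost its call without any 6 h control (highest 0.0734) or control 24 h replicate 1 (0.0909). ATP2B2 was also lost without control 6 h replicate 2 (0.158), and SOSTDC1 without replicate 3 (0.0742), and both after quantile normalization (0.0685 and 0.0556).

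Lists of mitosis, S phase and unfolded protein response genes had lower levels in the 24 h controls. Of 50 mitosis genes 14 fell, such as HJURP (−0.77) and CDC20 (−0.74), and 15 adjusted over the list alone. The median was −0.22 (adjusted p = 1.1e-05, adjusted p = 0.96 with an estimated correlation). Of 44 S phase genes 10 fell and 1 rose, such as MCM5 (−1.29) and MCM7 (−0.49), and 12 fell and 1 rose adjusted over the list alone. The median was −0.22 (adjusted p = 1.62e-05, adjusted p = 0.96 with an estimated correlation). In the unfolded protein response list 10 of 25 fell, such as the folding enzyme gene PDIA4 (−0.59) and HSPA5 (−0.63, SE 0.07, adjusted p = 6.99e-05), and 12 adjusted over the list alone. The median was −0.19 (adjusted p = 1.62e-05, adjusted p = 0.806 with an estimated correlation). Lower levels were also called for ATF4 genes (10 of 36 fell and 2 rose, 16 fell and 2 rose adjusted over the list alone, adjusted p = 0.00296, and adjusted p = 0.96 with an estimated correlation) and immediate early genes (6 of 26 fell, 8 fell and 1 rose adjusted over the list alone, adjusted p = 0.00493, and adjusted p = 0.96 with an estimated correlation). Mesenchymal markers, such as NES (−0.85) and TGFBI (−1.34), had 8 of 25 that fell and 1 that rose, 10 and 1 adjusted over the list alone (adjusted p = 0.028, adjusted p = 0.806 with an estimated correlation). Of 29 noradrenergic markers 6 fell, such as TBX2 (−0.50) and NPY (−0.56), and 2 rose, MYCN (0.99) and RET (0.70), with the same counts adjusted over the list alone, and the list did not pass (median 0.0046, adjusted p = 0.994). Cytosolic ribosomal proteins had a higher level, with RPL34 (0.37) the 1 called of 38, also adjusted over the list alone (adjusted p = 0.00315, adjusted p = 0.96 with an estimated correlation). The mesenchymal call was lost without control 6 h replicate 3 (0.079) or control 24 h replicate 2 (0.11), and the ribosomal call without control 24 h replicate 3 (0.271).

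In all, 1375 genes passed limma between the controls, 1356 of them with groups fully apart, as 32.6% of all genes were against 10% by chance, and 81 changed at least 2-fold. Over all arrays of each time the 18S signal was also higher at 24 h, by 1.66. In the controls alone its means were 11.6 at 24 h and 9.73 at 6 h. The count was 719 without control 6 h replicate 2, 832 without control 24 h replicate 1, 735 without control 24 h replicate 3 and 467 with the 3′ to 5′ ratio as a covariate, and centring each array on its median moved the share that rose from 32.2% to 44.9%. Of the 94 fibrillar risers 47 fell between the controls, where 7.44 would by chance, and of the 46 fallers 10 rose, where 1.73 would, but both comparisons use the same 24 h controls, whose noise enters them with opposite signs.

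**Figure D4:**
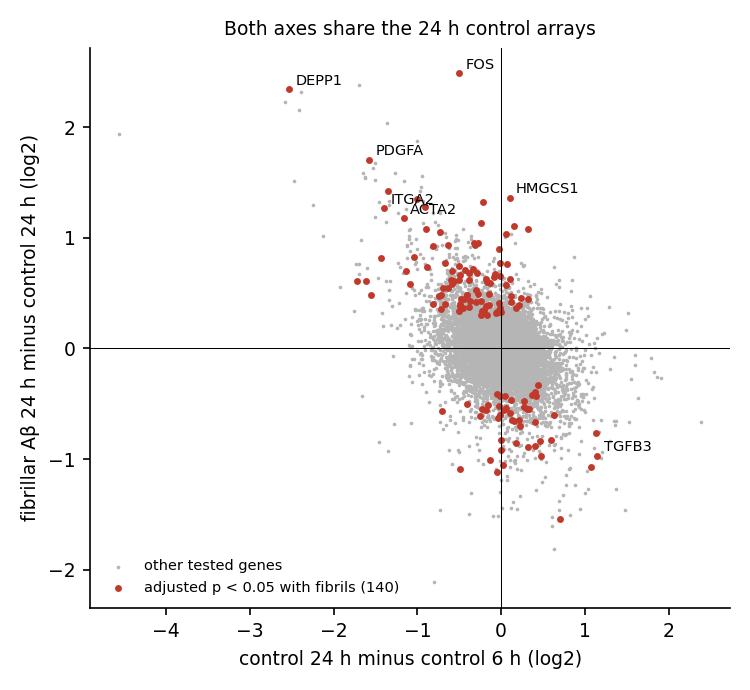
Log2 change with fibrillar Aβ at 24 h (vertical axis) against the log2 difference between the 24 h and 6 h controls (horizontal axis) for 11774 genes, with the 140 genes called with fibrils in red. Of these, 112 had opposite signs on the 2 axes, which share the 3 control arrays of 24 h.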

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

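The tests that leave out the highest fibrillar array and the test of RNA quality on the ATF4 list alone were chosen after the results were seen. ITGA2 (1.40), GTF2H3 (−1.22), SPDYE2 (−1.11), LPCAT1 (−0.77) and RNF145 (−0.65) stand here because their fibrillar and oligomeric responses differed in a test of the difference itself. So did the means of 4 lists, the immediate early genes (0.68), cholesterol genes (0.34), ATF4 genes (0.21) and hypoxia genes (0.10), but 0 lists passed with an estimated correlation (lowest adjusted p = 0.806 with an estimated correlation). Of the 5184 probe sets with several or no gene symbols, which the comparisons of genes leave out, 24 were called with fibrils, 7 higher and 17 lower, while limma called 0 with oligomers, where 201 had an unadjusted p below 0.05.

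For the fibrillar comparison 3 arrays against 3 allow 10 splits, too few for a share under 0.05, and the real split called 140 genes where the highest other called 2, a count that 1 of 10 splits reached. The same limit holds for the controls of both times, where the real split called 1375 and the highest other 1, a count that 1 of 10 reached. With oligomers the real split called 0, a count that all 10 splits reach whatever the data, and the highest other called 3. For the difference of the responses, 9 of 100 drawn splits within each time, the real one included, called as many as the real 5, with a highest other of 127. For the average 10 of 100, the real one included, called as many as the real 3, with a highest other of 127. So chance was not excluded for either count. But these shares cannot decide it, because drawn splits that keep the real 24 h groups carry the fibrillar difference. The high counts point to a structure of the arrays: 11 of the drawn splits kept the real groups at 24 h and mixed those at 6 h, and 7 of these reached the real count for the difference and 9 for the average, against 1 and 0 of the other drawn splits.

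The immediate early, cholesterol and ATF4 lists had higher levels with fibrils, calls that were all lost (adjusted p = 0.806 with an estimated correlation for each), and in each list fibrillar replicate 1 was the highest array. The rise was not confined to this array, since without it each list mean stayed at least 3.05 standard errors above 0. The means were then 0.38 for immediate early, 0.21 for cholesterol and 0.21 for ATF4 genes. But the lists had been called on these same arrays, so some remaining rise was built in. The immediate early standard error also went from 0.23 to 0.11 without the array. So this test gives no verdict on the cause of the rise. RNA quality, marked by the 3′ less 5′ values, stays open for the 3 lists together, since with it as a covariate the immediate early mean went from 0.67 (SE 0.23) to 0.41 (SE 0.21), 61.6% of its value, and the cholesterol mean from 0.32 (SE 0.09) to 0.20 (SE 0.07). For the ATF4 list alone 111% of the change was left, so these values did not account for its rise. That list was singled out after its result was seen, so no wider conclusion is drawn. A response to the fibrillar preparation stays open as the biological explanation and was untested. The controls had the same 24 h, so hours alone cannot give the rise. Whether it needs the form or the longer presence of the peptide cannot be told, because form and hours changed together. The immediate early and ATF4 lists were also called lower in the 24 h than in the 6 h controls, calls likewise lost with an estimated correlation. The rise is measured against those 24 h controls.

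Genes that rose with fibrils often fell between the controls, 47 of 94, and 112 of the 140 called genes had opposite signs. Noise in the 24 h controls, which both comparisons share, could account for the relation across all genes, since its covariance of −0.037 lay within that of 1000 simulated sets with no effects (mean −0.026, lowest −0.141), 252 of which lay at or below it. Whether a single control array adds to it was not decided, as the covariance without control 24 h replicate 1, the nearest to 0, was −0.045 where that of all arrays already lay within the simulated range. Against the 6 h controls the fibrillar arrays had a median of 0.22 for the risers and −0.48 for the fallers, whose median control change was 0.14. So fibrillar levels near those of the 6 h controls stay open as a biological explanation for part of the risers alone, with no test of it. Others, such as SH2D3C, HMGCS1 and FOS, had fibrillar means of 5.93, 9.07 and 6.50 against 4.81, 7.61 and 4.51 in the 6 h controls.

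The 24 h and 6 h controls differed in 1375 genes and also in 18S signal. An amplification or labelling difference marked by 18S cannot be told apart from an effect of time, since the slope of genes on the 18S signal within groups correlated with the control change at r = 0.140 across genes, inside the simulated 95% bounds of −0.149 and 0.160. Time itself stays open as the biological explanation and was untested.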

How the results depend on the processing

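The ratio covariate, the 24 h arrays alone with array weights and log2(signal + 16) were chosen after the data were seen. The offset fixed beforehand was for linear values and was not run. The oligomer count was 0 in all 21 other settings, with limma counts of 186 to 772 at an unadjusted p below 0.05. Of the values that answer a comparison, 145 stayed on their side of the threshold or within 1.5 times, 48 moved and 18 weakened, and 0 reversed. Of the values of single genes and other lists, 1058 stayed, 265 weakened and 5 became stronger. The fibril count moved from 140 to 79 with no filter, 62 with the mean of probe sets (57 shared), 7 with no trend (7 shared), 268 with array weights, 35 with only the 2 groups compared (31 shared), 74 with at least 1.5-fold, 269 with adjusted p below 0.10 and 39 with the ratio covariate (32 shared, 19 up and 20 down). With the 24 h arrays alone and array weights it was 143 (103 shared). The count for the difference of the responses moved from 5 to 3 with quantile normalization, 8 with log2(signal + 16), 3 with the mean of probe sets, 3 with every probe set, 0 with no trend, 27 with array weights, 20 with adjusted p below 0.10, 1 with the ratio covariate and 3 with the replicate block. Arrays with the same number deviated from their group means with correlations of −0.03 to 0.09, and 7 of 12 matched their own number best, among them 3 of 3 between fibrillar and control 24 h arrays, a hint from the data and not the design. With the block the fibril count was 184, and the oligomer list of mitosis genes was called lower (adjusted p = 0.0354). Limma had 1004 at an unadjusted p below 0.05 before any of these changes. The average count moved from 3 to 1 with the mean of probe sets, 0 with no trend, 6 with array weights and 1 with at least 1.5-fold, where 987 had an unadjusted p below 0.05. The control count moved from 1375 to 438 with at least 1.5-fold and 467 with the ratio covariate. Its share that rose was 32.2%, and 44.9% with median centring. With an estimated correlation the fibril lists weakened to an adjusted p of 0.806 for ATF4, NF-κB, immediate early and cholesterol genes, 0.927 for hypoxia and 0.96 for oxidative phosphorylation, and with fry to 0.138, 0.224, 0.222, 0.114, 0.322 and 0.728 in the same order. Oxidative phosphorylation weakened to 0.109 with median centring. Lists not called with all arrays and settings as first fixed were called without 1 array in 10 cases for oligomers, 1 of them in the other direction, 4 for fibrils, 9 for the difference and 4 for the average. Other settings called mitosis for fibrils (0.0401), oxidative phosphorylation for the difference (0.0137) and antioxidant enzymes for the average (0.0192), all lower with quantile normalization, and heat shock (0.0323) and splicing (0.0335) genes lower between the controls with no filter. With fry 4 more lists were called lower between the controls, while 5 of the 7 lost their call, ATF4 (0.114), immediate early (0.484), S phase (0.276), mitosis (0.33) and ribosomal protein genes (0.728). Leaving out single arrays gave 14 to 185 fibril genes, 0 to 64 for the difference, 1 to 32 for the average and 719 to 1106 for the controls. It gave an r between the responses from −0.0592 to 0.0394, and adjusted p-values from 1.29e-08 to 0.000221 for ATF4, 0.000816 to 0.149 for NF-κB, 1.44e-17 to 8.13e-06 for immediate early, 1.21e-12 to 2.41e-05 for cholesterol, 2.09e-05 to 0.24 for hypoxia and 0.00477 to 0.237 for oxidative phosphorylation. The 1.5-fold and adjusted p below 0.10 settings move counts by construction, no filter tests more genes, and the left-out arrays use fewer arrays. The 2 groups alone do too, yet with array weights the 24 h arrays gave 143, so the fall to 35 was not explained. The main fit shares 1 spread per gene between the 4 groups. For FOS, HMGCS1 and MATR3 the fibrillar SDs of 1.47, 0.69 and 1.03 were the largest, so the shared spread lies below theirs. For the same reason it can lie above the spread of the 6 h groups, as for APP. Elsewhere the cause was not tested. Signal near the background may limit the genes whose levels lie close to the filter, which was not tested either.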

Other observations

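The lists of actin, clock and FOXO genes were chosen after the fibrillar changes were seen, and the tests of them were written before their results. Genes named in these paragraphs were also chosen after their values were seen. With fibrils, 11 genes were called in each of the 6 fits that left out a 24 h array. Besides ITGA2, ACTA2, SPDYE2, KLF6, LPCAT1 and RNF145 they were RHOB, a small GTPase of actin and stress signalling (1.05), HGF, a growth factor (0.96), LONRF2 (0.78), VGLL4, a TEAD cofactor (0.63), and ACTN1, an actin cross-linking protein (0.62). RHOB, ACTN1 and LONRF2 fell between the 6 h and 24 h controls, by −0.73, −0.50 and −0.68.

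DEPP1, ACTA2 and ITGA2 had fibrillar levels of 4.44, 8.57 and 9.66, near the 6 h control levels of 4.63, 8.55 and 9.79 and above the 24 h control levels of 2.10, 7.39 and 8.40. SH2D3C, HMGCS1 and FOS instead had fibrillar levels of 5.93, 9.07 and 6.50, above the 6 h control levels of 4.81, 7.61 and 4.51. Over all 94 risers the fibrillar level had a median of 0.22 above the 6 h controls, and for the 46 fallers the median difference was −0.48.

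Since ACTA2, ACTN1 and RHOB rose, fibrils may shift actin genes regulated by SRF and MRTF. A list of such genes that left out the called ones had 19 of 23 members above 0 and a mean of 0.15 (95% interval 0.05 to 0.25), with an adjusted p of 0.00104 by camera over 9 tests. The rule written beforehand also asked for an unadjusted p under 0.05 with an estimated correlation, which was met (camera p = 0.00976). The unadjusted p with fry was 0.00135. After adjustment the call was lost (adjusted p = 0.0512 with an estimated correlation). That 0 members were called follows from leaving out the called genes. The list was chosen after actin genes had risen in the same arrays, so an actin shift stays open. The same list had a lower level in the 24 h than the 6 h controls (mean −0.30, 7 members called, adjusted p = 0.00104, and adjusted p = 0.0512 with an estimated correlation), which shares the 24 h controls, and did not pass with oligomers (adjusted p = 0.998).

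Clock genes may shift with fibrils too, with an adjusted p of 0.0269 by camera, 11 of 14 members above 0 and a median of 0.14. With an estimated correlation the unadjusted p of 0.035 met the rule, but the adjusted p was 0.105. The unadjusted p with fry was 0.00623. The mean of 0.29 rests in large part on CRY2 (2.22, adjusted p = 0.17), and 0 members were called by limma. For FOXO targets, which DEPP1 brought to mind, the adjusted p was 0.049 with a mean of 0.12, 13 of 18 members above 0 and 2 called, IRS2 (0.34) and CDKN1B (0.33). That call was lost too (adjusted p = 0.26 with an estimated correlation), so a FOXO shift stays open.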
